A study of Mus musculus with 8 samples.

How the data were processed

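Total RNA of whole geniculate ganglia, the sensory ganglia that hold the cell bodies of the taste neurons of the anterior tongue and palate, was measured by RNA-seq in 4 wild type littermates and 4 Egr4 knockout mice. Per the labels' protocols, the libraries were made from 1 ng of RNA with a SMART-Seq kit and a Nextera XT kit and sequenced as read pairs of 150 bp. The labels do not describe a step that marks strand or molecular identifiers, so reads of overlapping genes on opposite strands cannot be told apart and PCR copies were not removed by identifier. The labels give the material as all cells of the ganglion, so a level is an average over neurons, glia, vessels, connective tissue and any neighbouring tissue carried along.

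The submitters' processing notes name FastQC 0.11.5, STAR 2.5, featureCounts of Subread 1.5.1 and edgeR 3.12.1, and the mouse build mm10. Each gene has a raw read count per library in the table that the authors deposited. The same table holds log2 FPKM values that the authors derived from the counts. Recomputing log2 FPKM from the counts, the deposited gene lengths and TMM-scaled library sizes gave differences of at most 0.0035 over the 5330 genes with 1000 or more counts in every library. The authors' deposited table also gives a fold change, a log2 fold change, a p-value and a false discovery rate per gene for knockout against wild type. It lists 15110 genes, and the lowest value found for a gene's fourth-highest library was 0.502 CPM, so genes under some level are not analysed here. The mitochondrially encoded genes and the Y-linked genes of the lists were not analysed here either. The per-library log2 FPKM values served only for that check, and all tests here used the raw counts.

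Total counts ran from 30849310 to 54255872 per library. Every gene passed the default filterByExpr filter, so 0 genes were removed. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit with robust dispersion, quasi-likelihood F-test, two-sided), with genotype as the only factor. P-values were adjusted by Benjamini-Hochberg over all 15110 genes and called at 0.05. Standard errors are the fitted log2 fold change divided by the square root of the F statistic, and intervals are at 95%. Levels are TMM-scaled CPM, given as mean ± SD over the 4 libraries of a group. Single values were compared by a two-sided exact permutation test of log2 CPM with a prior count of 2. It has 70 arrangements, and the smallest p it can give is 0.0286. Where a group had no count of a gene, the fold was computed against a floor of 3 counts over the whole group. Intervals on ratios of counts and such floors cover counting error only.

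Before the data were examined, 33 gene lists were fixed for ganglion neuron classes, other cell types that a dissection could hold, and response genes. The 31 lists with at least 3 measured genes were tested with camera (limma 3.58.1) on log2 CPM at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry were run beside it. The genes named were also fixed by rule. They are Egr4, the 5 taste quality markers, up to 10 called genes per direction with an absolute log2 fold change of at least 1 and no overlap between groups, and up to 4 members with the smallest p from each list camera called and each neuronal or receptor list. The rule leaves out predicted genes and sex-linked genes of the lists, and 2 genes that it names are not reported here. The 10 genes called in the authors' deposited table are named besides these and were chosen after their values were seen.

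The alternatives fixed beforehand were RLE factors, library size alone, no filter, at least 1 CPM in 4 libraries, the edgeR likelihood ratio test, the quasi-likelihood test without robust dispersion, DESeq2 1.42.0, limma-voom, replicate number as a block, Xist class as a covariate, each library left out in turn, other thresholds, and other windows around Egr4. Xist alone set the sex class. Further alternatives were added after seeing the data. These left out library 4 of both genotypes together, used edgeR's newer quasi-likelihood deviances, used Xist class in the list tests, and used an unadjusted p near Egr4. The replicates came from separate mice, and the smallest chi-square per degree of freedom between 2 libraries of a group was 124, so no library was a copy of another. Exons of the 68 named genes were compared with the GENCODE annotation of the same build, and 16 of the 68 share exon bases with another gene.

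The tests were tried on simulated counts drawn from the real means, dispersions and library sizes, in 5 simulations of 15110 genes. For knockout against wild type with 4 simulated libraries each, 15.4% of genes changed 2-fold, 68.9% of those changed 4-fold and 80.6% of those changed 8-fold were called, and 31 of 572 calls were false. Over the 5 simulations, 331, 331 and 325 genes were changed by these folds. Where many genes change, the Benjamini-Hochberg cutoff is easier to pass. The real comparison called 1 gene, so these rates can overstate what it would recover. A gustatory neuron list shifted 2-fold was called by camera at the preset correlation in 5 of 5 simulations, and 2 of 150 tests of other lists were called. The simulated genes varied independently, while the estimated correlation within the real gustatory list was 0.107. The simulations therefore do not show how often camera calls a list falsely when its members vary together.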

Results

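The series measured gene expression in the geniculate ganglion of adult mice of the C57Bl/6 strain that carry or lack Egr4, a zinc finger transcription factor of the early growth response family. Its title names the neurons for sweet and umami taste, so the comparison asks how the ganglion's expression, and its taste neuron genes in particular, differs without Egr4. There were 4 wild type and 4 knockout libraries, each from a separate mouse. Wild type libraries 1 to 4 held 48571434, 30849310, 45577436 and 44922468 counts, and knockout libraries 1 to 4 held 49791511, 43267322, 54255872 and 43192969 counts. Xist, the transcript of the inactive X chromosome, had 0 counts in wild type library 4 and knockout libraries 1 and 2, and 177 or more in each of the other 5, so both sexes were present in both genotypes.

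Egr4 (chromosome 6, 85511122 to 85513542, mm10, 2 merged exons) stood at 2.21 ± 1.16 CPM in wild type and 0.912 ± 0.332 CPM in knockout ganglia (SD, n = 4 each). The log2 fold change was -1.27 (95% interval -2.71 to 0.16), with an adjusted p of 0.924 in edgeR's quasi-likelihood test. Wild type library 3, at 0.925 CPM, lay below 3 of the 4 knockout libraries, which ran from 0.444 to 1.22 CPM. The exact permutation p was 0.114. Counts over the whole gene do not show which part of Egr4 was deleted, so reads from a remaining part of the transcript would be counted too, and the values neither check nor contradict the genotype labels.

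None of the 5 markers of taste quality classes passed the test. Spon2, a marker of sweet neurons, stood at 6.76 ± 1.15 CPM in wild type and 8.11 ± 4.41 CPM in knockout ganglia (SD, n = 4 each), a log2 fold change of 0.26 (95% interval -0.68 to 1.21). Cdh4, a marker of umami neurons, stood at 6.19 ± 4.84 and 7.36 ± 4.81 CPM, a log2 fold change of 0.25 (95% interval -1.21 to 1.71). The bitter marker Cdh13 had a log2 fold change of 0.20 ± 0.30 (SE), the salt marker Egr2 one of 0.14 ± 0.32 (SE) and the sour marker Penk one of 0.29 ± 0.32 (SE). Of the 5, 0 were called by edgeR's quasi-likelihood test (smallest adjusted p = 0.924, for Penk), 0 had an unadjusted p under 0.05, 0 were called over the list alone, and 0 were called by the likelihood ratio test, DESeq2 or limma-voom. The intervals for Spon2 and Cdh4 leave room for a change of over 2-fold upward, and for Cdh4 also downward. Within each genotype Egr2 was highest in library 3 (115 CPM in wild type, 135 CPM in knockout) and lowest in library 4 (44.5 and 61.1 CPM). So was the mean log2 CPM of the myelinating Schwann cell list, at 8.96 and 8.64 in library 3 and 8.04 and 7.56 in library 4. In whole ganglia the level of Egr2 need not be that of salt neurons alone.

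**Figure D1:**
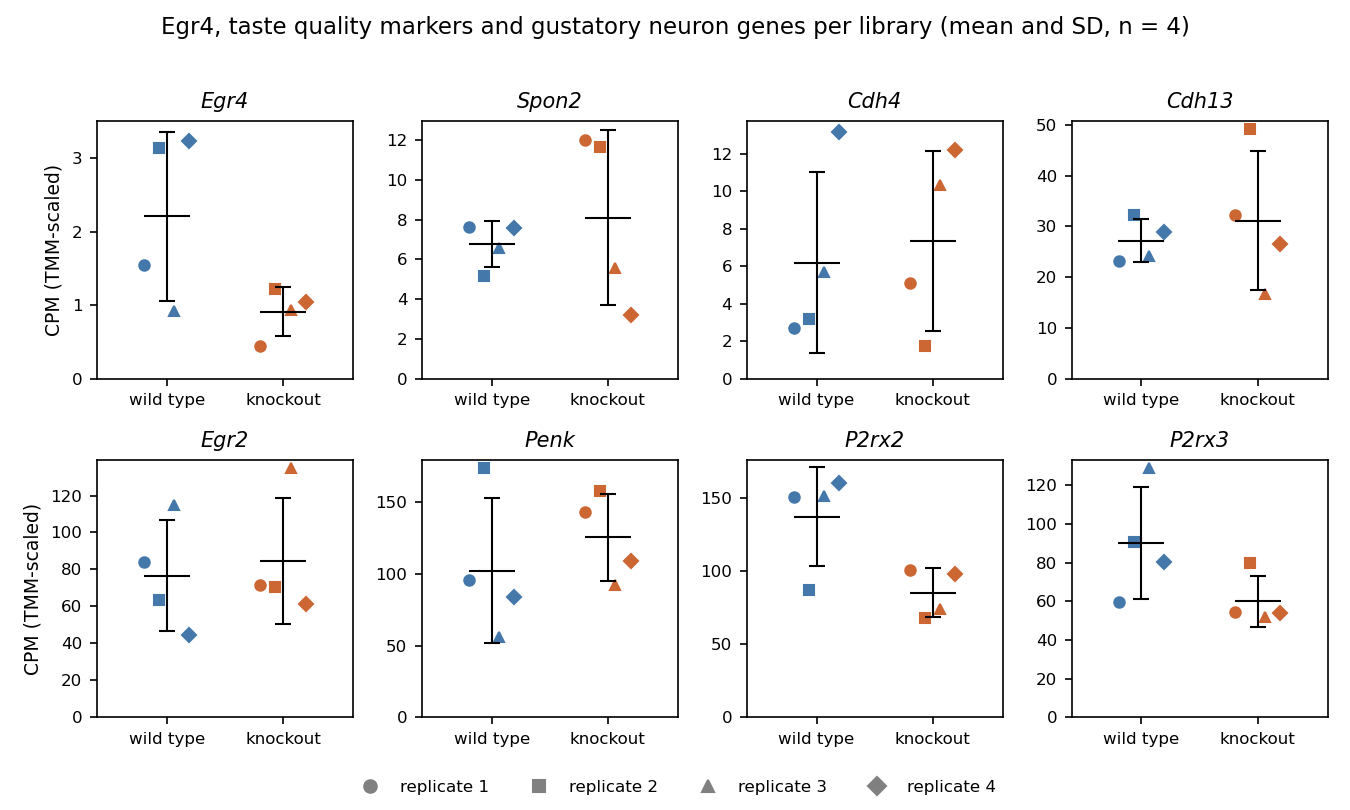
TMM-scaled CPM of Egr4, the 5 taste quality markers and the gustatory neuron genes P2rx2 and P2rx3 in each library, by genotype; symbols mark replicate numbers, horizontal bars the mean and vertical bars the SD (n = 4). The knockout libraries overlap the wild type libraries in every panel, with P2rx2 between 67.9 and 101 CPM in knockout and between 86.7 and 160 CPM in wild type ganglia.

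The list of gustatory neuron identity was called lower in the knockout by camera at its preset correlation (adjusted p = 0.040), but not with an estimated correlation (adjusted p = 0.850) or by fry (adjusted p = 0.783). Its library means overlapped between genotypes, with a mean log2 CPM of 5.43 ± 0.210 in wild type and 5.25 ± 0.194 in knockout ganglia (SD, n = 4 each, exact permutation p = 0.257). P2rx2, a subunit of the ATP receptor through which taste buds signal to their nerves, was at 137 ± 33.8 CPM in wild type and 85.1 ± 16.7 CPM in knockout ganglia (SD, n = 4 each), a log2 fold change of -0.69 ± 0.22 (SE). P2rx3, the other subunit, had a log2 fold change of -0.59 ± 0.24 (SE), and Gfra1, a receptor for GDNF, one of -0.68 ± 0.29 (SE). Of the 16 members, 12 had negative and 4 positive log2 fold changes, 0 were called over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. DESeq2, limma-voom and the likelihood ratio test called 0 of them. The camera call was lost without any one of wild type libraries 1, 3 and 4 and knockout libraries 2 and 3, where the adjusted p reached 0.188.

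The other neuronal and receptor lists were not called by camera. The 24 pan-neuronal genes had a median log2 fold change of 0.02, with Syt1 at -0.48 ± 0.23 (SE) and Vsnl1 at 0.86 ± 0.62 (SE). Their mean log2 CPM ran from 7.04 to 8.26 between libraries and was highest in wild type library 4 and knockout libraries 1, 3 and 4. The comparisons of taste quality markers and of the gustatory list were not adjusted for this. Among trophic factor genes, Nrtn, which encodes neurturin, stood at 8.35 ± 2.21 CPM in wild type and 16.3 ± 2.71 CPM in knockout ganglia (SD, n = 4 each). It was the 1 of 13 members that passed when adjusted over the list alone, and its receptor Gfra2 had a log2 fold change of -0.78 ± 0.34 (SE). The nicotinic receptor subunit Chrna5 had a log2 fold change of 1.58 ± 0.47 (SE) and the T-type calcium channel Cacna1h one of -1.03 ± 0.27 (SE), each without overlap between genotypes. Among somatosensory genes, Piezo2, a mechanosensitive channel, had a log2 fold change of -0.72 ± 0.27 (SE), and Scn10a, a sodium channel of nociceptors, stood at 3.54 ± 1.60 CPM in wild type and 0.517 ± 0.834 CPM in knockout ganglia. None of these genes was called over all genes, where their adjusted p in edgeR's quasi-likelihood test was 0.924 or higher.

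Over all genes, 1 of 15110 was called. Wdfy1 (chromosome 1, 79702262 to 79761769, 17 merged exons), which encodes a FYVE domain protein of endosomes, rose from 9.01 ± 2.79 CPM in wild type to 49.7 ± 8.94 CPM in knockout ganglia (SD, n = 4 each). Its log2 fold change was 2.46 (95% interval 1.87 to 3.06), with an adjusted p of 0.0477 in edgeR's quasi-likelihood test, and all 4 knockout libraries (38.0 to 59.3 CPM) lay above all 4 wild type libraries (5.59 to 12.4 CPM). No gene was called lower: 0 genes passed, 438 genes had a negative log2 fold change and an unadjusted p under 0.05, and the likelihood ratio test, DESeq2 and limma-voom called 6, 7 and 0 genes lower. In both directions together, 731 genes had an unadjusted p under 0.05, where 755.5 are expected by chance, and 2.62% of genes had groups that did not overlap, where chance gives 2.86%. The count at an unadjusted p under 0.05 depended on the fit, from 411 without wild type library 3 to 1123 without wild type library 4 and 1452 with the replicate block. The call of Wdfy1 was lost in 7 of the 8 fits that left out 1 library, all but the one without wild type library 4, with an adjusted p of up to 0.415, and also with RLE factors, without TMM and with Xist class as a covariate. Its log2 fold change stayed between 2.29 and 2.66 over all 20 alternative fits. Wdfy1 shares 126 bp of exon with Mrpl44 on the other strand.

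The authors' deposited table calls 10 genes, 4 higher and 6 lower, at a false discovery rate under 0.05. The edgeR likelihood ratio test run on the deposited counts called the same 10. Apart from Wdfy1, none passed the quasi-likelihood test. Siglecg (chromosome 7, 43408280 to 43418349), an inhibitory lectin of B cells, had 447 counts over the wild type and 1 count over the knockout libraries, a ratio of 486 (95% counting interval 86.7 to 19220), with an adjusted p of 0.108 in edgeR's quasi-likelihood test. Nlrp12 (chromosome 7, 3221510 to 3249740), a NOD-like receptor of myeloid cells, had 286 counts in wild type and 0 in knockout, at least 104-fold lower against a floor of 3 counts over the group, with an adjusted p of 0.685 in edgeR's quasi-likelihood test. Dbp (chromosome 7, 45705247 to 45710203), a transcription factor of the circadian clock's output, stood at 18.6 ± 2.34 CPM in wild type and 40.9 ± 7.74 CPM in knockout ganglia (SD, n = 4 each), a log2 fold change of 1.14 ± 0.20 (SE); it shares 539 bp of exon with Sphk2 on the other strand. Klhl31, a kelch protein of striated muscle, had 5 counts in wild type and 799 in knockout. Knockout library 4, the highest in skeletal muscle genes, stood at 14.4 CPM and the other 3 at 0.741 to 2.04 CPM. Wild type library 3 had a higher mean log2 CPM of the muscle list (2.47) than knockout libraries 1 (1.305) and 3 (1.89). Its Klhl31 level was nonetheless 0.043 CPM, against 0.741 CPM in knockout library 1 and 1.05 CPM in knockout library 3.

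The other lower calls of the authors' deposited table were Robo2, Plxnb3, Draxin and Lzts1. Robo2, a receptor for Slit proteins, stood at 42.7 ± 6.13 CPM in wild type and 20.7 ± 3.28 CPM in knockout ganglia (SD, n = 4 each), a log2 fold change of -1.05 ± 0.19 (SE). The semaphorin receptor Plxnb3 stood at 19.2 ± 7.70 and 5.77 ± 1.27 CPM, and Draxin, a repulsive guidance protein, at 1.60 ± 0.673 and 0.0481 ± 0.0815 CPM. Of the 39 measured members of the axon guidance list, 25 had negative and 14 positive log2 fold changes, 7 had an unadjusted p under 0.05, and 1, Robo2, passed when adjusted over the list alone. Camera did not call the list (adjusted p = 0.117). Lzts1, a leucine zipper protein, had 166 counts in wild type and 4 in knockout. The noncoding Gm13749 (chromosome 1, 63964727 to 63968999), a higher call, had 7 and 147.

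**Figure D2:**
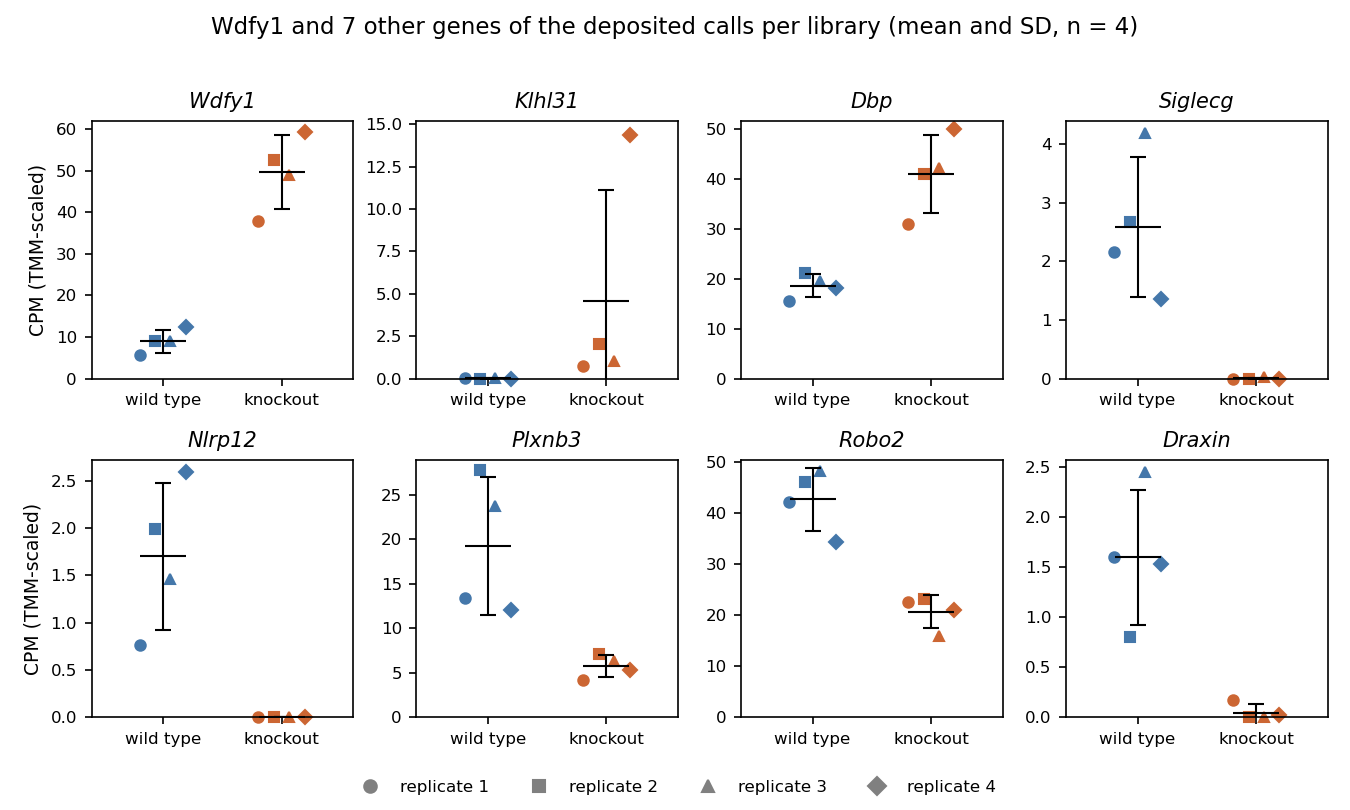
TMM-scaled CPM of Wdfy1 and 7 other genes called in the authors' deposited table, in each library by genotype; symbols mark replicate numbers, horizontal bars the mean and vertical bars the SD (n = 4), and the lower end of the SD bar of Klhl31 lies below the axis. The genotypes do not overlap in any panel, with Wdfy1 at 5.59 to 12.4 CPM in wild type and 38.0 to 59.3 CPM in knockout ganglia.

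Lists of other cell types made up 6 of the 8 lists that camera called at its preset correlation. None of the 8 was called with an estimated correlation (adjusted p = 0.850 for each) or by fry (smallest adjusted p = 0.783), and the library means of every one of them overlapped between genotypes. All 12 choroid plexus and meningeal genes had positive log2 fold changes (adjusted p = 6.32e-05 by camera, adjusted p = 0.850 with an estimated correlation). Among them Ttr, the transthyretin of choroid plexus, stood at 918 CPM in knockout library 2, at 80.8 to 184 CPM in the other knockout libraries and at 51.1 to 88.5 CPM in wild type. Its log2 fold change was 2.34 ± 0.68 (SE), and 1.01 without knockout library 2. All 15 genes of myelinating Schwann cells had negative log2 fold changes (adjusted p = 0.000348 by camera, adjusted p = 0.850 with an estimated correlation), among them Mag at -0.97 ± 0.42 and Mbp at -0.67 ± 0.30 (SE). All 10 measured skeletal muscle genes had positive ones (adjusted p = 0.000348 by camera, adjusted p = 0.850 with an estimated correlation), with Acta1 at 622 CPM in knockout library 4 and at most 24.2 CPM elsewhere. So had all 12 endothelial genes (adjusted p = 0.00164 by camera, adjusted p = 0.850 with an estimated correlation), with Pecam1 at 189 CPM in knockout library 2 and at most 40.2 CPM elsewhere.

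Of 13 central glia genes, 10 had negative and 3 positive log2 fold changes (adjusted p = 0.0371 by camera, adjusted p = 0.850 with an estimated correlation), with Ermn at -1.38 ± 0.57 and Mobp at -1.05 ± 0.58 (SE). This list and that of Schwann cells shifted the same way, and levels in whole ganglia do not tell which of these cells Mag and Mbp came from. All 12 genes of bone marrow and neutrophils had negative ones (adjusted p = 0.045 by camera, adjusted p = 0.850 with an estimated correlation), with Mmp9 at -1.29 ± 0.55 (SE) and at -0.57 without library 4 of each genotype. Besides the gustatory list, camera also called the list of axon injury and regeneration (adjusted p = 0.0265, adjusted p = 0.850 with an estimated correlation). In it 17 of 18 members had negative log2 fold changes, such as Stmn4 at -0.82 ± 0.24 and Sprr1a at -1.25 ± 0.69 (SE). Of the 432 genes in any tested list, 0 were called over all genes. When adjusted over the list alone, 7 skeletal muscle genes passed, and so did Ly6c1 of the endothelial, Nrtn of the trophic factor, Robo2 of the axon guidance and Cfd of the adipocyte list, the last chosen for mention after its value was seen.

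Single libraries decided several of these camera calls. The bone marrow call was lost without any one of wild type libraries 3 and 4 and knockout libraries 3 and 4 (adjusted p up to 0.794), with the replicate block (adjusted p = 0.219) and without TMM (adjusted p = 0.0868), and without library 4 of each genotype the list turned upward (adjusted p = 0.203). With Xist class as a covariate, by contrast, its adjusted p by camera at the preset correlation of 0.01 fell to 4.15e-09. The estimated correlation within this list, without Xist class, was 0.946, far above the preset value. The list was not tested with both Xist class and an estimated correlation, so this small p does not establish a shift. The central glia call was lost without any one of wild type libraries 1 and 2 and knockout libraries 3 and 4 (adjusted p up to 0.342), without TMM (adjusted p = 0.0515) and without library 4 of each genotype (adjusted p = 0.203). The axon injury call was lost without wild type library 1, wild type library 2 or knockout library 3 (adjusted p = 0.121, 0.0594 and 0.188 by camera). The endothelial call was lost without knockout library 2 (adjusted p = 0.264), and the muscle call was lost without library 4 of each genotype (adjusted p = 0.0965). Leaving out library 4 of each genotype and using Xist class in the list tests were chosen after seeing the data.

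**Figure D3:**
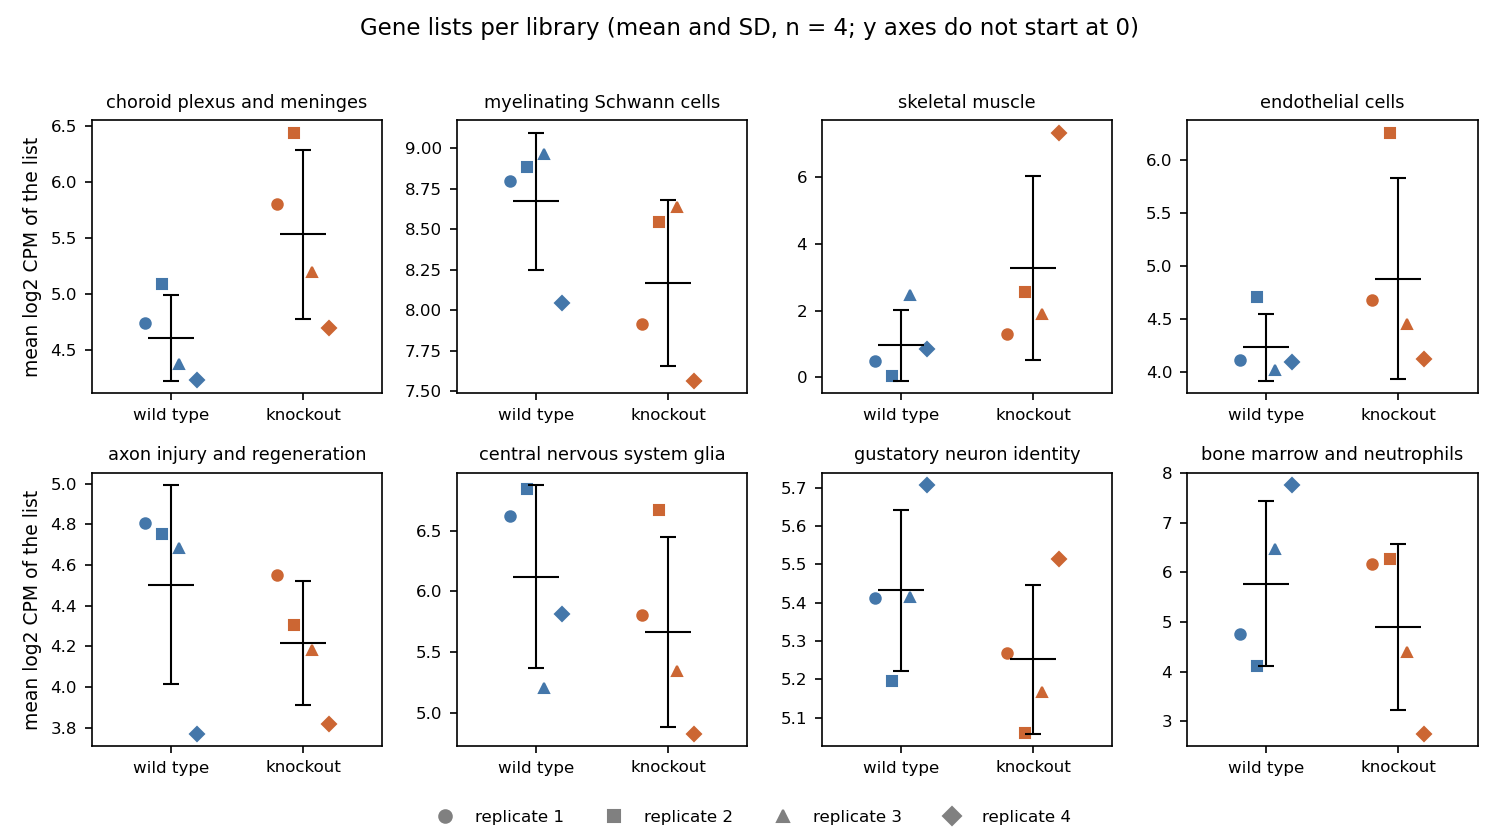
Mean log2 CPM of the 8 lists called by camera in each library, by genotype; symbols mark replicate numbers, horizontal bars the mean and vertical bars the SD (n = 4), and the axes do not start at 0. The genotypes overlap in every panel, and knockout library 4 reaches 7.34 in skeletal muscle genes, where the other libraries lie between 0.026 and 2.55.

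Genes that neighbour a targeted gene can come from the strain of the embryonic stem cells, so genes within 10 Mb of Egr4 on chromosome 6 were compared with the rest. Of 133 tested genes in that window, 0 were called by edgeR's quasi-likelihood test, against 1 of 14977 elsewhere (Fisher's exact test, two-sided, p = 1). Likewise 0 were called by the likelihood ratio test, DESeq2 or limma-voom. At an unadjusted p under 0.05 there were 5 genes in the window, or 3.76%, and 4.85% elsewhere (odds ratio 0.767, 95% interval 0.244 to 1.84). With 1 call in the whole genome, the comparison of called genes cannot show an excess.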

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

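In 13 of 152 groups of 4 values, 1 library lay far from the other 3, where chance gives about 7.6. The gap to the nearest library is given as a share of the group's whole range. Knockout library 2 was highest in the endothelial genes Pecam1 (0.942) and Esam (0.836) and in P2rx3 (0.885). Wild type library 4 was lowest in Piezo2 (0.921), Ugt8a (0.843) and the mean of axon injury and regeneration genes (0.881), and highest in Vsnl1 (0.888). Wild type library 2 was lowest in P2rx2 (0.898) and Scn10a (0.849) and highest in the mean of endothelial genes (0.869), and wild type library 3 was highest in Acta1 (0.877). Siglecg in knockout library 3 and Lzts1 in knockout library 1 each gave 1, since the other 3 libraries of the group had no count.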

How the results depend on the processing

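The alternatives with Xist class in the list tests, without library 4 of both genotypes, with newer deviances and with an unadjusted p near Egr4 were chosen after seeing the data. The count of called genes was 1 (1 higher, 0 lower). It was 0, with 0 higher, with RLE factors, library size alone, Xist class as a covariate and without both libraries 4. The adjusted p of Wdfy1 was 0.0519 with RLE factors, in a range of 3.26e-14 to 0.415 over all 20 fits. DESeq2 called 14 genes (7 higher, 7 lower) and edgeR's likelihood ratio test 10 (4 higher, 6 lower). The cause of these differences was not tested. The count was 1 with limma-voom, without robust dispersion, with newer deviances, with the stricter filter, with both other thresholds and without the genes near Egr4; the default filter removes no gene, so the fit without it tests nothing. With the replicate block 2 genes were called, Wdfy1 and Irg1, of which 1, Irg1, was lower. Whether the replicate numbers pair the libraries was not settled. Same-numbered libraries correlated at 0.0606, 0.149, 0.004 and 0.0632. Those of replicates 1 and 2 correlated best with their own number (-0.00248 and -0.034 for the best other), and those of replicates 3 and 4 better with another number (0.0531 and 0.0692). Leaving out 1 library gave 0 to 1 called genes, 0 to 1 higher and 4 to 12 lists. The 8 lists called by camera became 0 with fry and with an estimated correlation, and 4 without both libraries 4. With Xist class they became 11, the added ones being erythroid cells (adjusted p = 0.000318), macrophages (adjusted p = 0.0223) and T and B lymphocytes (adjusted p = 0.0184), all lower in the knockout at the preset correlation. The library means of these 3 lists overlapped between genotypes. Without Xist class none was called by camera, at the preset correlation (adjusted p = 0.114, 0.112 and 0.611) or with an estimated correlation (adjusted p = 0.850 each). The calls with Xist class were not tested with an estimated correlation. The count of genes at an unadjusted p under 0.05, 731 in the main fit, ran from 411 to 1452 over the 20 fits. Egr4 stayed uncalled, at -1.53 to -1.03 on the log2 scale, and 0 of the 5 taste quality markers were called in any of the 20 fits. Near Egr4, 5 genes passed at an unadjusted p. Uncalled genes that changed sign were Spon2 (-0.15) and Cdh13 (-0.024) with Xist class, and Prtn3 (0.30) and Ltf (0.29) without both libraries 4. Over fits that left out 1 library, Cdh4 ran from -0.11 to 0.93, Cdh13 from -0.12 to 0.40, Egr2 from -0.18 to 0.39 and Prtn3 from -1.58 to 0.019. Of 1327 comparisons of single genes, 1290 kept direction and side of the threshold, 16 passed it, 11 fell short of it and 10 reversed. Counts limit the folds of Nlrp12, Siglecg, Lzts1, Klhl31, Gm13749 and Draxin, which had 0 to 9 counts in 1 genotype.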

Other observations

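Apart from the count of genes and of lists over other splits and the count of neighbours within 5 Mb, the tests in this part were chosen after their results, or part of them, had been seen. Genes of cholesterol synthesis were picked after Cyp51 and Hmgcs1, both members, were seen near the top of the gene table of this same comparison, so no p is given for the group. All 19 had negative log2 fold changes, with Hmgcs1, Cyp51 and Idi1 among them, and a median of -0.543. Over all genes, 0 were called and 14 had an unadjusted p under 0.05 in edgeR's quasi-likelihood test. Their mean log2 CPM was 6.76 ± 0.304 in wild type and 6.22 ± 0.0796 in knockout ganglia (SD, n = 4 each), and the lowest wild type library, at 6.334, and the highest knockout library, at 6.326, lay close together. The mean of the 15 myelinating Schwann cell genes differed by -0.505 and that of the cholesterol genes by -0.541 on the log2 scale (knockout minus wild type). Unlike the cholesterol means, the Schwann cell means overlapped between genotypes, at 8.04 to 8.96 in wild type and 7.56 to 8.64 in knockout libraries. The like size of both shifts therefore does not show that they have the same source.

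The libraries differed widely in some single genes, in part along lines that did not match genotype. Calb2, a calcium-binding protein, was at 7.20, 19.98 and 11.8 CPM in wild type libraries 1 to 3 and 15.4 CPM in knockout library 2, and at 1139, 370, 1046 and 796 CPM in wild type library 4 and knockout libraries 1, 3 and 4. Pvalb was at 11.5 to 32.0 CPM in the first 4 of these and at 352 to 512 CPM in the others. Prl, the pituitary hormone prolactin, was at 2648 CPM in wild type library 1, 355 CPM in wild type library 3 and 2276 CPM in knockout library 3, and at most 21.3 CPM in the other 5. Calb1, also a calcium-binding protein, parted the libraries as Calb2 and Pvalb did. It was at 467, 151, 598 and 593 CPM in wild type library 4 and knockout libraries 1, 3 and 4, and at most 37.7 CPM elsewhere. Which cells these transcripts came from was not tested. The Purkinje cell genes Car8, Pcp2 and Ppp1r17 were high in knockout libraries 3 and 4 alone, so they did not go with Calb1 in wild type library 4 and knockout library 1. Car8 was at 107 and 329 CPM there and at most 12.8 CPM elsewhere, Pcp2 was at 18.8 and 41.8 CPM there and at most 3.15 CPM elsewhere, and Ppp1r17, which DESeq2 called between genotypes, was at 20.9 and 36.9 CPM there and at most 3.14 CPM elsewhere.

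Chance was not excluded for either count by the other ways of splitting the 8 libraries. The real split called 1 gene, and 2 of the 35 splits into 4 and 4 called as many. The highest of the others, which set wild type libraries 1 to 3 and knockout library 2 against the rest, called 226 genes. The libraries thus have a structure other than genotype, and it parts them as Calb2, Pvalb and Calb1 do. It is not independent of genotype, since the rest holds knockout libraries 1, 3 and 4 but only wild type library 4. The mean log2 CPM of the 24 pan-neuronal genes was 7.77 to 8.26 in that rest and 7.04 to 7.62 in the other libraries. This structure may therefore tilt comparisons of neuronal genes between genotypes. The real split called 8 lists, 17 of the 35 splits called as many, and the highest of the others called 14.

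Wdfy1, Siglecg and Nlrp12 lie on chromosomes 1 and 7 and kept the genotypes apart in every library. Fewer neutrophils in the knockout would lower Nlrp12, but 3 of the 4 knockout libraries lay above the lowest wild type library in the neutrophil mean: S100a8 was at 250 CPM in knockout library 1 with no Nlrp12 count, and at 44.3 CPM in wild type library 2 with 64 counts of Nlrp12. Fewer B cells were argued against in the same way for Siglecg, since 2 knockout libraries lay above the lowest wild type library in the mean of 4 B cell genes, with Cd79a at 31.1 CPM in knockout library 2 and 6.21 CPM in wild type library 2. Sequence of another strain carried along with Egr4 was argued against, since 0 of the 3 genes lie within 20 Mb of it. Separate segments of another strain at the 3 loci could not be decided, with an odds ratio of 0.916 for an unadjusted p under 0.05 among the 247 genes within 5 Mb (95% interval 0.449 to 1.68), and an effect of Egr4 itself also stays open. Gm13749, also called in the authors' deposited table, lies on chromosome 1 as Wdfy1 does, but outside the 5 Mb around it. Of 3 genes known to differ between substrains of C57Bl/6, Nnt was at 36.3 CPM in wild type and 41.7 CPM in knockout ganglia, Ide at 58.0 and 56.1 CPM and Entpd4 at 4.50 and 4.81 CPM, with overlap between genotypes for each. These lie on chromosomes 13, 19 and 14, so they do not test the 3 loci.

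Dbp was higher in all 4 knockout libraries than in any wild type library, and dissection at another time of day is a candidate explanation. The signed mean of 11 other clock genes, counted as positive where they go with Dbp, was 1.49 ± 0.134 in wild type and 1.99 ± 0.143 in knockout libraries (SD, n = 4 each), a shift of 0.495 on the log2 scale (exact permutation p = 0.0286, the smallest it can give). Nr1d1, a clock repressor, had a log2 fold change of 0.62 ± 0.19 (SE) and Npas2 one of -1.27 ± 0.58 (SE), while Clock stood at 0.01 ± 0.32 (SE). Tef stood at 0.04 ± 0.26 (SE), and Bhlhe41, counted as going with Dbp, at -0.09 ± 0.25 (SE). None of the 11 was called over all genes. The set was chosen after related values had been seen, so its p is not that of a test fixed beforehand. The labels used here give no time of collection, so time of day and genotype stay open together, as does a local effect near Siglecg, which lies 2.30 Mb from Dbp.

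The shifts of cell type lists may come from unequal amounts of neighbouring tissue in single dissections. For 6 of the 6 called cell type lists the library means overlapped between genotypes. A single library had the largest mean log2 CPM by a gap in several. It was knockout library 4 in muscle genes (7.34, the next 2.55) and knockout library 2 in endothelial genes (6.26, the next 4.70). In bone marrow genes it was wild type library 4 (7.75, the next 6.47), and in choroid plexus genes, by less, knockout library 2 (6.44, the next 5.80). In the lists of myelinating Schwann cells and central glia no single library had the largest mean by a wide gap. An effect of genotype on these cells cannot be told apart from this, since the calls of 3 of the 6 lists were lost without some single library (endothelium, central glia, bone marrow) and the calls of the other 3 held at the preset correlation. Those 3 were choroid plexus and meninges, myelinating Schwann cells and skeletal muscle, with an adjusted p by camera of at most 0.0495 in any of the 8 fits that left out 1 library, though the muscle call was lost without library 4 of each genotype. With an estimated correlation (adjusted p = 0.850 each) or by fry (adjusted p = 0.783 each) none of the 3 was called.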
